A study of Homo sapiens with 14 samples.

How the data were processed

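RNA sequencing of total RNA extracted with TRIzol was analysed from 14 libraries of the pancreatic cancer cell lines Panc-1 and AsPC-1, 7 conditions in each: untreated mock, and ANG or EGF for 1, 5 or 24 h in serum-starved cells. The groups were taken from the labels, and each group held 1 library. The deposited files list 23040 genes with symbol, chromosome, strand, start, end and log2 RPKM, so the unit is a log2 value that the authors computed from reads per kilobase per M mapped reads, per the file headers. The genome build is hg19, per the submitters' processing notes. The aligner, the counting tool, the annotation version and whether strand was used are not given in the sources used here. All coordinates are those of the files, in hg19 and counted from 1, and span introns. Gene names are the files' own symbols, some of them older ones (SC4MOL is MSMO1, SEPP1 is SELENOP).

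The log2 values were turned back to RPKM, where 95.8% of the values under 5 RPKM lay within 0.1 of a step of 0.01, and the lowest log2 value of -8.966 was read as a listed RPKM of 0. Depth was estimated from the files, since the value of 1 read in a gene depends on gene length and library depth. The steps of genes with a span of at most 150 bp were whole multiples, within 0.1, of 1 read for 99.5 to 100% of values. They gave 11.2 to 23.8 M reads (median 17.8), at which 1 read in 2 kb of transcript is worth 0.0210 to 0.0448 RPKM (median 0.0282). Genes with a span under 400 bp took 5.11 to 17.2% of the reads. Counts per gene were not rebuilt, because transcript lengths are not in the files, and no count model was used.

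Tests used limma 3.58.1 in R 4.3.3, with a trend of variance on mean level, on log2(RPKM + 1) of the 13427 genes with at least 1 RPKM in at least 2 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. A fold change is on the log2(RPKM + 1) scale, with a pseudocount of 1, and understates the change of low genes. Each condition was compared with mock in an additive model of cell line and condition over all 14 libraries. ANG and EGF were compared within 6 pairs of line and time, times within 4 courses of line and ligand, and the lines within the 7 conditions, and the dependence of a difference on line or ligand was tested as an interaction. The lines are the only repeat, so the spread in the comparisons with mock is how the conditions differ between 2 lines, and a response present in a single line counts as spread. Values of 1 treated library against the mock of its line carry no test. They are given as counts of genes at least 2-fold apart and as medians of gene lists with their percentile among 10000 random lists.

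Before the data were examined, the design, the alternatives, 26 gene lists and the rule for naming genes were fixed. The rule took, per comparison, the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of at least 1 RPKM and the same direction in every line, pair or course, or 5 each way where none passed. Symbols of unnamed loci, microRNAs, small nucleolar RNAs and pseudogenes were skipped. It added up to 4 members of each list with the largest change and always EGFR, ANG, EGF, RNH1, PLXNB2, FOS, EGR1, DUSP6, MYC, CCND1 and CDKN1A. Of the genes it took, 2 are not reported here. MIR15A and MIR339 were named outside the rule, after their values were seen. The fixed test for count tables was not needed, as the files hold RPKM, and the limma test fixed for that unit was used.

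Gene lists were tested in the limma fits with camera at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. ANG against EGF and the comparison of the lines were tested with an exact two-sided sign-flip test of the list's median per pair, with 64 and 128 sign patterns and smallest p values of 0.031 and 0.016. Lists with fewer than 3 measured members were not tested. Correlations of changes across genes and overlaps of calls or of 2-fold sets that share a mock library are given beside simulations of unchanged libraries sharing that mock, 20 of them for the overlaps. The noise of the overlap simulations is the residual spread of the additive model, which also holds responses that differ between the lines. That of the correlation simulations is the residual spread of ANG against EGF within pairs, which uses no mock library. Equal noise in every library fixes the simulated r, so only the simulated covariance depends on that spread.

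The procedure was tested on simulated data for 13427 genes, 200 of them changed, with the residual spread of each comparison's own fit. In the 6 comparisons of a condition with mock, 41 to 57% of genes changed 2-fold and 77 to 87% of those changed 4-fold were recovered. For ANG against EGF 92% and 98% were recovered, for 24 h against 1 h 68% and 96%, for the lines 77% and 92%, and for the ligand-dependent change over time 0% and 19%. False calls made up 2.17 to 8.09% of the calls in the 6 simulated comparisons with mock (lowest for ANG at 24 h, highest for EGF at 1 h) and 4.52% in that of ANG with EGF.

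Alternatives were centring of each library on its median, no filter beyond a nonzero value, limma without the trend, a pseudocount of 0.1, leaving out each library, pair or course in turn, a list's mean in place of its median, and correlations over the upper part of the expression range. Other alternatives were chosen after seeing the data: genes of at least 400 bp rescaled to their own total, leaving out the 24 h or the 1 h and 5 h libraries, single lines and single ligands, and camera for ANG against EGF. Values of genes with near-identical copies (histones, HSPA1A and HSPA1B, ribosomal proteins), of overlapping or antisense genes and of genes near the length of a read are uncertain.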

Results

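Transcript levels were measured by RNA sequencing of total RNA in 2 human pancreatic cancer cell lines, Panc-1 and AsPC-1. Serum-starved cells were treated with epidermal growth factor (EGF, 50 ng/ml), the ligand of the receptor EGFR, or with angiogenin (ANG, 1 µg/ml), a secreted ribonuclease that the series title names as a ligand of EGFR. Cells were sampled after 1, 5 or 24 h, and each line also had 1 untreated (mock) library whose time was not given in the labels. The 14 libraries thus formed 7 conditions per line with 1 library each. No condition had a repeat within a line, so every test below used the 2 lines, the 6 ANG and EGF pairs, or the 4 time courses as its repeats, and its p-values measure only the spread between these libraries. Depth estimated from the value of a single read was 11.2 to 16.8 M reads in Panc-1 (median 15.1) and 18.8 to 23.8 M in AsPC-1 (median 21.1), and 11192 to 12266 genes reached 1 RPKM (reads per kilobase per M mapped reads) per library. The doses differ between the ligands, so the comparison of ANG with EGF is one of 2 treatments at single doses.

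EGFR, the receptor itself (hg19, chromosome 7, 55086725 to 55275031), was listed at 32.4 to 43.7 RPKM in Panc-1 and at 84.5 to 149 RPKM in AsPC-1. The gene of the ligand EGF (chromosome 4, 110834040 to 110934118) was listed at 0.02 RPKM at most in every library. The ANG gene (chromosome 14, 21152336 to 21162345), whose span overlaps that of RNASE4 and whose reads are therefore uncertain, was at 2.64 to 4.93 RPKM in Panc-1 and 1.56 to 3.14 RPKM in AsPC-1. The ribonuclease inhibitor RNH1 and the ANG receptor PLXNB2 were abundant in both lines, with RNH1 at 87.1 to 96.1 RPKM in Panc-1 and 71.3 to 96.7 in AsPC-1. In both lines the 1 h and 5 h libraries stood apart from the mock and 24 h libraries. The 1 h and 5 h libraries of ANG were closer to each other (Euclidean distance over all genes 23.8 in Panc-1 and 24.1 in AsPC-1) than to the EGF library of the same time (34.8 and 30.7 in Panc-1, 30.6 and 47.8 in AsPC-1). On the first principal component within Panc-1, the 1 h and 5 h libraries lay between 19.7 and 24.0, and the mock and 24 h libraries between -34.1 and -22.9. In AsPC-1 the 1 h and 5 h libraries lay between 29.1 and 45.7, and the mock and 24 h libraries between -56.5 and -29.5. Over all genes the library nearest to mock was that of 24 h of ANG in AsPC-1 (distance 28.2, against 57.1 for 24 h of EGF) and that of 24 h of EGF in Panc-1 (40.0, against 41.1 for 24 h of ANG). All these distances include genes under 400 bp. In Panc-1 such genes took 6.22% of the reads in mock, 16.5% at 24 h of ANG and 11.6% at 24 h of EGF. They took 5.11% at 1 h of EGF in Panc-1 and 5.29% at 5 h of EGF in AsPC-1, against 10.0% and 17.2% with ANG. Because mock grouped with 24 h in both lines and the time of the mock libraries was not given, each comparison of 1 h or 5 h with mock also holds that split.

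**Figure D1:**
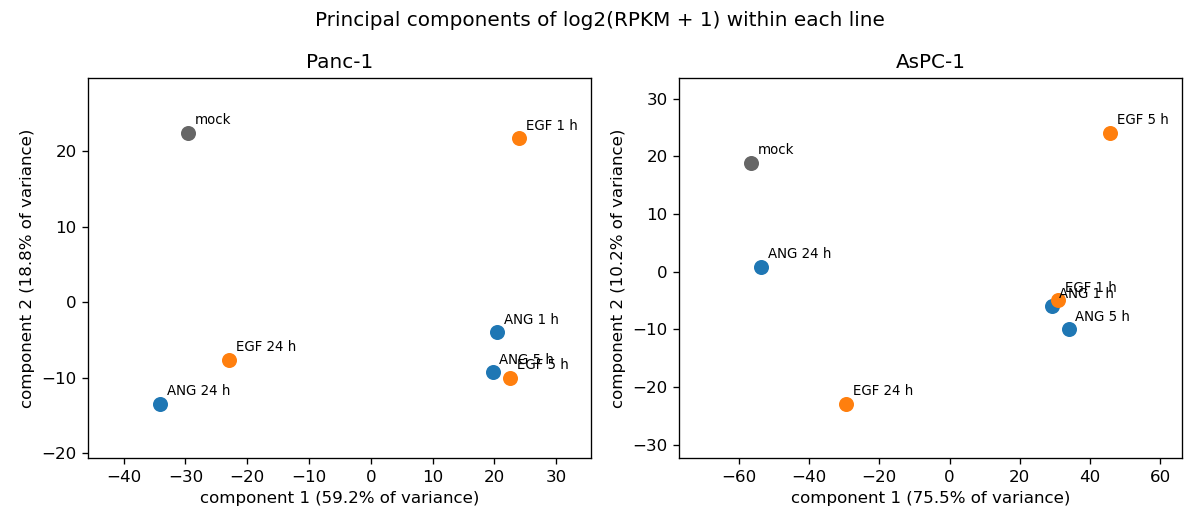
First and second principal components of log2(RPKM + 1) within Panc-1 (59.2% and 18.8% of the variance) and within AsPC-1 (75.5% and 10.2%), 1 point per library, with mock in grey, ANG in blue and EGF in orange. In both panels the 1 h and 5 h libraries of either ligand lie on one side and the mock and 24 h libraries on the other.

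To find the early transcripts of EGF treatment, the 1 h EGF libraries were compared with the mock library of the same line. Of the 21 measured immediate-early genes 7 passed, all of them higher in 2 of 2 lines. EGR1, a zinc finger transcription factor (chromosome 5, 137801181 to 137805004), went from 1.32 to 29.1 RPKM in Panc-1 and from 5.40 to 42.4 RPKM in AsPC-1, a log2 fold change of 3.23 ± 0.36 (SE; limma adjusted p = 0.0259). The AP-1 genes FOSB (3.64 ± 0.59), FOSL1 (2.39 ± 0.41) and JUN (2.01 ± 0.32) and the nuclear receptor NR4A1 (3.48 ± 0.46) also rose in 2 of 2 lines (limma adjusted p = 0.0438, 0.0499, 0.0438 and 0.0315). In the same libraries genes of cholesterol synthesis fell, among them SC4MOL (-1.5 ± 0.17), DHCR7 (-1.46 ± 0.16) and FDFT1 (-1.25 ± 0.18). The fatty acid desaturase FADS2 (-1.81 ± 0.23) and PIK3IP1 (-1.65 ± 0.27), an inhibitor of PI3 kinase, fell too. Of 13427 genes tested, 28 rose and 61 fell, and 2308 had an unadjusted p under 0.05. With each library centred on its own median, 19 rose and 16 fell.

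Of the 21 measured immediate-early genes, 7 rose, 0 fell and the others did not pass, and 16 rose adjusted over the list alone. The list's median was 1.35 (limma's camera, adjusted p = 3.88e-20; adjusted p = 0.0531 with an estimated correlation). The median was 1.63 in Panc-1 and 1.07 in AsPC-1, each at percentile 100 among 10000 random lists of the same size and matched expression. FOS itself did not pass (1.63 ± 0.42, adjusted p = 0.114), nor did MYC (0.95 ± 0.29, adjusted p = 0.153) or the cell cycle inhibitor CDKN1A (1.34 ± 0.43, adjusted p = 0.165). Of the 21 measured genes of cholesterol synthesis, 0 rose and 5 fell over all genes, and 13 fell adjusted over the list alone (median -0.69, camera adjusted p = 5.82e-09; adjusted p = 0.123 with an estimated correlation). Of 31 genes of RNA polymerase I and ribosome biogenesis, RRP12, a factor of ribosomal subunit export, rose (1.71 ± 0.25), and 12 rose adjusted over the list alone (median 0.51, camera adjusted p = 9.32e-13; adjusted p = 0.123 with an estimated correlation). Of 16 genes of the unfolded protein response, the endoplasmic reticulum chaperone HSPA5 (0.97 ± 0.16) and SDF2L1 (0.78 ± 0.13) rose, and 5 did so adjusted over the list alone (median 0.29, camera adjusted p = 6.09e-06; adjusted p = 0.123 with an estimated correlation). Of 13 FOXO target genes, 1 fell (PIK3IP1) and 4 fell adjusted over the list alone (median -1.16, with -0.10 in Panc-1 and -1.92 in AsPC-1). Of 22 interferon-stimulated genes 0 passed over all genes and 6 fell adjusted over the list alone (median -0.58, camera adjusted p = 4.05e-04; adjusted p = 0.123 with an estimated correlation).

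Other genes that rose after 1 h of EGF included the transcription factor CSRNP1 (1.81 ± 0.19), the polo-like kinase PLK3 (1.73 ± 0.21) and the transcriptional regulator SERTAD1 (1.59 ± 0.22). Those that fell included the MYC antagonists MXD4 (-1.46 ± 0.16) and MXI1 (-1.26 ± 0.21), PBXIP1 (-1.43 ± 0.21), the autophagy-related coactivator CALCOCO1 (-1.25 ± 0.17) and the ephrin EFNA3 (-1.25 ± 0.19). The MAPK feedback genes as a list had 0 members past the test over all genes and 2 that rose adjusted over the list alone, and its median of 0.24 joined 0.54 in Panc-1 with -0.39 in AsPC-1. DUSP6, an ERK phosphatase, went from 7.47 to 46.0 RPKM in Panc-1 and from 215 to 72.9 RPKM in AsPC-1 and did not pass (0.46 ± 0.90, adjusted p = 0.822). In the same libraries the G2/M genes stood at a median of 1.53 above mock in Panc-1 and -2.63 from mock in AsPC-1. The calls rested on every library used: without the Panc-1 mock, the Panc-1 1 h EGF library or the AsPC-1 mock 0 genes passed, without the AsPC-1 1 h EGF library 2 passed, and with all 24 h libraries left out, a choice made after seeing the data, 0 passed.

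After 5 h of EGF 3 of the 21 immediate-early genes were past the test on the higher side, and 11 of the 21 genes of cholesterol synthesis on the lower side. EGR1 stood at 3.30 RPKM in Panc-1 and 7.33 RPKM in AsPC-1 and did not pass (0.64 ± 0.36, limma adjusted p = 0.328), while FOSL1 (2.17 ± 0.41, adjusted p = 0.0319) and JUN (1.49 ± 0.32, adjusted p = 0.0426) were past the test in 2 of 2 lines. S100A2, a calcium-binding protein (2.56 ± 0.49), TNFRSF12A, the TWEAK receptor (1.98 ± 0.24), the glycosyltransferase B3GNT5 (1.41 ± 0.17), the nuclease AEN (1.32 ± 0.20) and the urokinase gene PLAU (1.42 ± 0.32, adjusted p = 0.0496) rose. The acetyl-CoA acetyltransferase ACAT2 (-2.54 ± 0.48), FADS2 (-2.13 ± 0.23), PIK3IP1 (-1.89 ± 0.27), the epithelial transcription factor ELF3 (-1.71 ± 0.26), the sulfite oxidase SUOX (-1.71 ± 0.15) and the insulin receptor INSR (-1.67 ± 0.34) fell. In all 80 genes rose and 487 fell, with 2994 at an unadjusted p under 0.05. With each library centred on its median 72 rose and 96 fell, and without any 1 of the 4 libraries compared 0 passed.

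By list, 3 of the 21 immediate-early genes rose after 5 h of EGF and 4 rose adjusted over the list alone (median 0.58, camera adjusted p = 6.02e-07; adjusted p = 0.179 with an estimated correlation). Of the 21 cholesterol genes 11 fell and 13 fell adjusted over the list alone, with SC4MOL at -1.66 ± 0.17, DHCR7 at -1.58 ± 0.16, FDFT1 at -1.46 ± 0.18 and FDPS at -1.32 ± 0.13 (median -0.97, camera adjusted p = 8.80e-09; adjusted p = 0.179 with an estimated correlation). Of 12 invasion and urokinase system genes PLAU rose and 4 rose adjusted over the list alone (median 1.37, camera adjusted p = 8.54e-07; adjusted p = 0.304 with an estimated correlation), with a median of 0.33 in Panc-1 and 2.07 in AsPC-1. Of 22 interferon-stimulated genes 2 fell, and 10 fell adjusted over the list alone (median -0.62). Of 17 p53 target genes 3 fell over all genes, among them TP53INP1 (-1.19 ± 0.19) and BTG2 (-0.98 ± 0.20), while adjusted over the list alone 1 rose and 4 fell. Of 31 ribosome biogenesis genes 2 rose and 5 rose adjusted over the list alone (median 0.41). Of 73 ribosomal protein genes 2 fell, RPL13A (-0.84 ± 0.15) among them, although reads of these genes can be shared with processed copies and their values are uncertain. Of 16 unfolded protein response genes 2 rose, with HSPA5 at 1.13 ± 0.16, and 3 rose adjusted over the list alone. Of 20 genes of ATF4 and amino-acid stress SLC3A2, an amino-acid transporter subunit, rose (0.96 ± 0.22), and of 17 epithelial markers TJP3 (-1.19 ± 0.27) and ELF3 fell. Of 13 FOXO targets INSR and PIK3IP1 fell and 6 fell adjusted over the list alone. The receptor gene ERBB2 (-1.70 ± 0.39, adjusted p = 0.0507), CDKN1A (1.82 ± 0.43, adjusted p = 0.0537) and MYC (1.13 ± 0.29, adjusted p = 0.0683) did not pass. In these libraries the G2/M median was 1.37 from mock in Panc-1 and -3.74 in AsPC-1.

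After 24 h of EGF 0 genes passed with limma, and 961 had an unadjusted p under 0.05. The genes at the ends of the ranking, none past the test, were the growth factor gene BMP6 (1.68 ± 0.53), CDKN1A (1.29 ± 0.43), the phosphatase ALPPL2 (-1.74 ± 0.57), the carboxypeptidase inhibitor LXN (-1.65 ± 0.74) and the selenoprotein SEPP1 (-1.58 ± 0.49). Among lists, the median of the invasion genes was 0.82 (camera adjusted p = 3.54e-10; adjusted p = 0.365 with an estimated correlation), that of the ATF4 genes 0.40 (camera adjusted p = 3.61e-06; adjusted p = 0.454 with an estimated correlation) and that of the FOXO targets -0.61 (camera adjusted p = 0.0291; adjusted p = 0.672 with an estimated correlation). Cholesterol genes had a median of 0.08. These medians lay farther from 0 in AsPC-1 than in Panc-1: 1.29 against 0.37 for the invasion genes, 0.66 against 0.034 for the ATF4 genes and -0.97 against -0.21 for the FOXO targets. In the average of the 3 EGF times 30 genes were higher than mock and 138 lower (2645 at an unadjusted p under 0.05), and this average also holds the split of 1 h and 5 h from mock. The higher genes included FOSL1 (1.80 ± 0.33, adjusted p = 0.0482), TNFRSF12A (1.46 ± 0.20, adjusted p = 0.0397), RRP12 (1.23 ± 0.20) and the immediate-early gene IER2 (0.99 ± 0.12). The lower ones included PIK3IP1 (-1.49 ± 0.22), FADS2 (-1.36 ± 0.19) and ELF3 (-1.15 ± 0.21). Of the 21 immediate-early genes 2 were higher in the average and 10 adjusted over the list alone, and of the 21 cholesterol genes 5 were lower and 11 adjusted over the list alone. The average lost all of its calls with centred libraries, and without either mock, either Panc-1 library of 1 h or 5 h, or the AsPC-1 library of 5 h or 24 h, and 2 genes passed without the AsPC-1 library of 1 h.

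**Figure D2:**
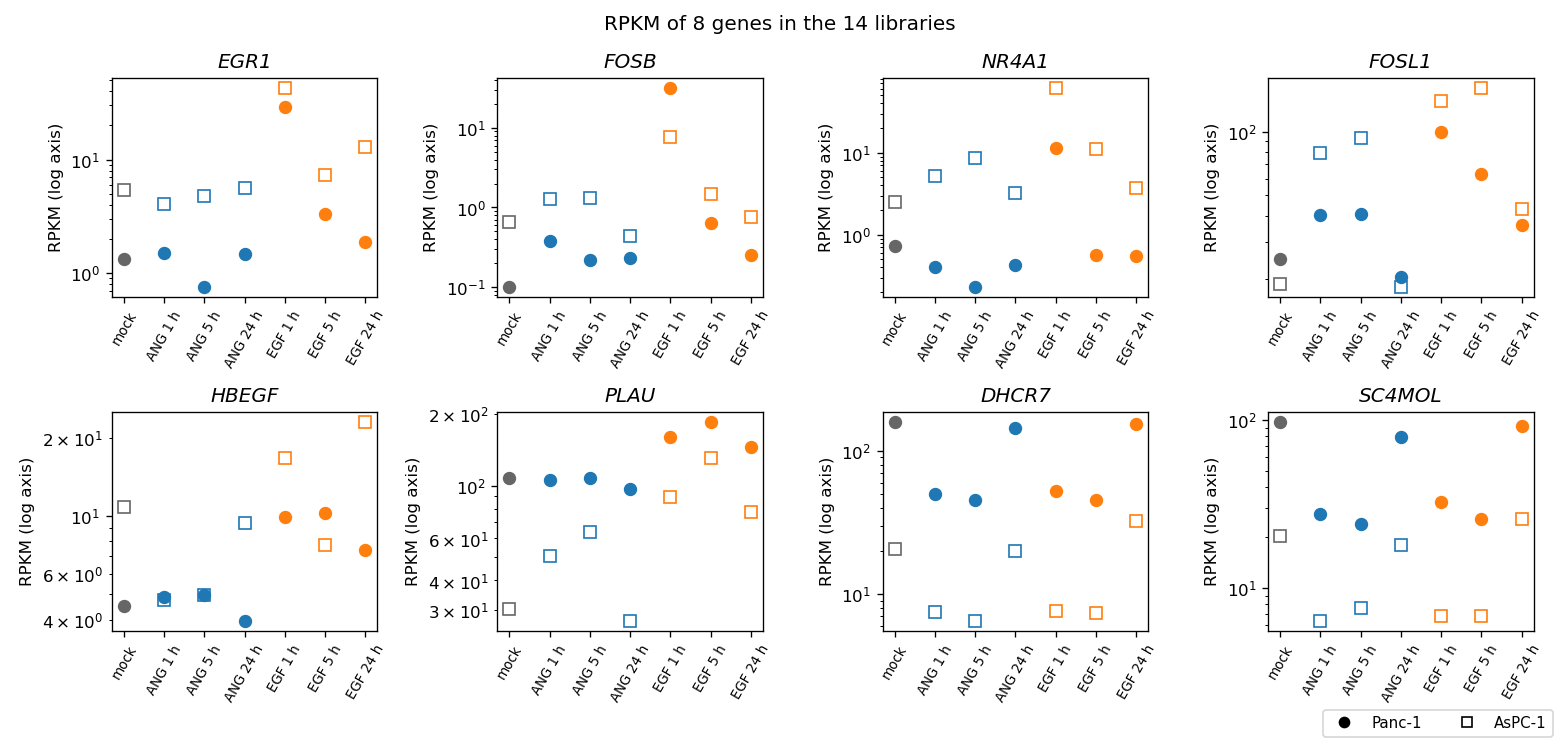
RPKM (log axis) of 8 genes in each library, with Panc-1 as filled circles and AsPC-1 as open squares. EGR1, FOSB and NR4A1 peaked in the 1 h EGF libraries of both lines (29.1 and 42.4 RPKM for EGR1), and DHCR7 and SC4MOL were low at 1 h and 5 h of either ligand.

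The same comparison for ANG asked which transcripts followed ANG treatment. After 1 h of ANG 0 genes rose and 11 fell (limma, 2062 at an unadjusted p under 0.05), all lower in 2 of 2 lines, and 4 of them belong to cholesterol synthesis. FADS2 went from 159 to 53.3 RPKM in Panc-1 and from 22.2 to 3.62 RPKM in AsPC-1 (log2 fold change -1.94 ± 0.23, adjusted p = 0.0361). The sterol enzymes SC4MOL (-1.66 ± 0.17), DHCR7 (-1.5 ± 0.16), IDI1 (-1.37 ± 0.15) and FDPS (-1.19 ± 0.13) fell, as did SREBF2, the transcription factor of the sterol pathway (-1.04 ± 0.11). The other named genes were the calcium channel subunit CACNB3 (-1.27 ± 0.15), the GTPase-activating protein ARAP1 (-1.10 ± 0.13), the phosphatase regulator IGBP1 (-1.05 ± 0.13) and PHLDB1 (-1.04 ± 0.12). After 5 h of ANG 0 genes rose and 15 fell (2392 at an unadjusted p under 0.05). They included FADS2 (-2.05 ± 0.23, adjusted p = 0.0270), DHCR7 (-1.65 ± 0.16), SC4MOL (-1.63 ± 0.17), IDI1 (-1.51 ± 0.15), FDPS (-1.39 ± 0.13) and FDFT1 (-1.39 ± 0.18, adjusted p = 0.0486), and also SUOX (-1.16 ± 0.15) and the phosphatidate phosphatase LPIN1 (-1.13). With centred libraries, without the 24 h libraries (a choice made after seeing the data), or without any 1 of the 4 libraries compared, 0 genes passed at either time.

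Of the 21 cholesterol genes 4 fell after 1 h of ANG and 15 fell adjusted over the list alone (median -0.95, camera adjusted p = 2.56e-13; adjusted p = 0.158 with an estimated correlation). After 5 h 5 fell and 15 fell adjusted over the list alone (median -1.06, camera adjusted p = 9.67e-13; adjusted p = 0.130 with an estimated correlation). The immediate-early genes did not pass: 0 of 21 rose or fell at 1 h or 5 h of ANG, also adjusted over the list alone. At 5 h camera ranked the list upward (adjusted p = 0.00392; adjusted p = 0.597 with an estimated correlation) with a median of 0.02. EGR1 stood at 1.49 RPKM in Panc-1 and 4.07 RPKM in AsPC-1 after 1 h (-0.12 ± 0.36, adjusted p = 0.896) and FOS at 0.82 and 5.11 RPKM (-0.35 ± 0.42, adjusted p = 0.719). FOSL1 was higher in both lines without passing (1.34 ± 0.41, adjusted p = 0.186), as was MYC (0.74 ± 0.29, adjusted p = 0.281). Ribosome biogenesis genes had a median of 0.43 at 1 h with 0 members past the test over all genes and 2 that rose adjusted over the list alone (camera adjusted p = 6.55e-11; adjusted p = 0.208 with an estimated correlation). The medians of the interferon-stimulated genes were -0.59 at 1 h and -0.65 at 5 h, with 5 and 9 members that fell adjusted over the list alone (camera adjusted p = 1.99e-04 and 1.20e-04; adjusted p = 0.158 and 0.142 with an estimated correlation). The unfolded protein response genes had a median of 0.25 at both times, and 2 rose adjusted over the list alone at each. EGFR itself was lower without passing (-0.51 ± 0.23, adjusted p = 0.331), as was the ANG gene (-0.55 ± 0.16, adjusted p = 0.174). Of the 5 genes of ANG and its partners 0 passed at 1 h over all genes and 1 fell adjusted over the list alone. In these libraries the G2/M median was 1.58 and 1.54 above mock in Panc-1 and -3.03 and -3.22 from mock in AsPC-1.

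After 24 h of ANG 0 genes passed with limma, 202 had an unadjusted p under 0.05, and 0 of the lists were called. Unchanged genes would give a share of 0.05 of the 13427 tested, which is more than 202. The spread of this fit also holds the changes at 1 h and 5 h that differed between the lines, so small changes can be missed. The genes at the ends of the ranking were the structural RNAs RPPH1 (1.54 ± 0.72) and RMRP (1.14 ± 0.73), the snoRNA host SNHG7 (1.39 ± 0.58) and the crystallin CRYGS (-0.67 ± 0.24), none past the test. EGR1 (0.07 ± 0.36), FOS (-0.01) and EGFR (-0.17) were near mock. Of genes with a span of at least 400 bp and a mean of at least 1 RPKM over the 2 libraries, 7 differed by at least 2-fold from mock in Panc-1 and 4 in AsPC-1. All of them were higher. These libraries had more reads in short genes than mock: the median log2 ratio of small nucleolar RNAs of the H/ACA class to mock was 1.66 in Panc-1 and 0.98 in AsPC-1. In the average of the 3 ANG times 0 genes differed from mock (limma, smallest adjusted p = 0.0619, 1789 at an unadjusted p under 0.05), with SC4MOL at -1.17, IDI1 at -1.09 and DHCR7 at -1.08 at that smallest value. Adjusted over the list alone, 14 of the 21 cholesterol genes (median -0.74) and 9 of the 22 interferon-stimulated genes fell. The immediate-early list had a median of -0.02 and a mean of 0.08 in this average, and camera ranked it upward (adjusted p = 0.0194; adjusted p = 0.862 with an estimated correlation). Across these comparisons with mock the median of all genes tested lay at -0.13, -0.17 and -0.09 for ANG and at -0.12, -0.16 and -0.13 for EGF at 1, 5 and 24 h.

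To compare the ligands directly, each ANG library was set against the EGF library of the same line and time, which removes the mock libraries and the time split. FOSL1, IER2 and MCL1 of the immediate-early genes, the urokinase gene PLAU and the EGFR ligand gene HBEGF were lower with ANG. HBEGF, itself an EGFR ligand (chromosome 5, 139712428 to 139726188), stood at 4.88 RPKM with ANG and 9.87 RPKM with EGF at 1 h in Panc-1 and at 4.74 and 16.7 RPKM in AsPC-1 (fitted difference -0.99 ± 0.13, limma adjusted p = 0.0382). The AP-1 gene FOSL1 differed by -0.91 ± 0.09 (adjusted p = 0.0193) and the survival gene MCL1 by -0.91 ± 0.12 (adjusted p = 0.0408). PLAU (-0.88 ± 0.11), IER2 (-0.85 ± 0.11), PHLDA2 (-0.84 ± 0.09), TNFRSF12A (-0.78 ± 0.08), B3GNT5 (-0.77 ± 0.07) and the cytokine LIF (-0.76 ± 0.10) were also lower, with adjusted p between 0.0193 and 0.0446, each in 6 of 6 pairs. In all 19 genes were lower with ANG and 2 were higher, and 2146 had an unadjusted p under 0.05. The 2 higher genes, MIR15A (1.95) and MIR339 (1.18), are microRNA genes, short enough for single reads to weigh and uncertain.

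**Figure D3:**
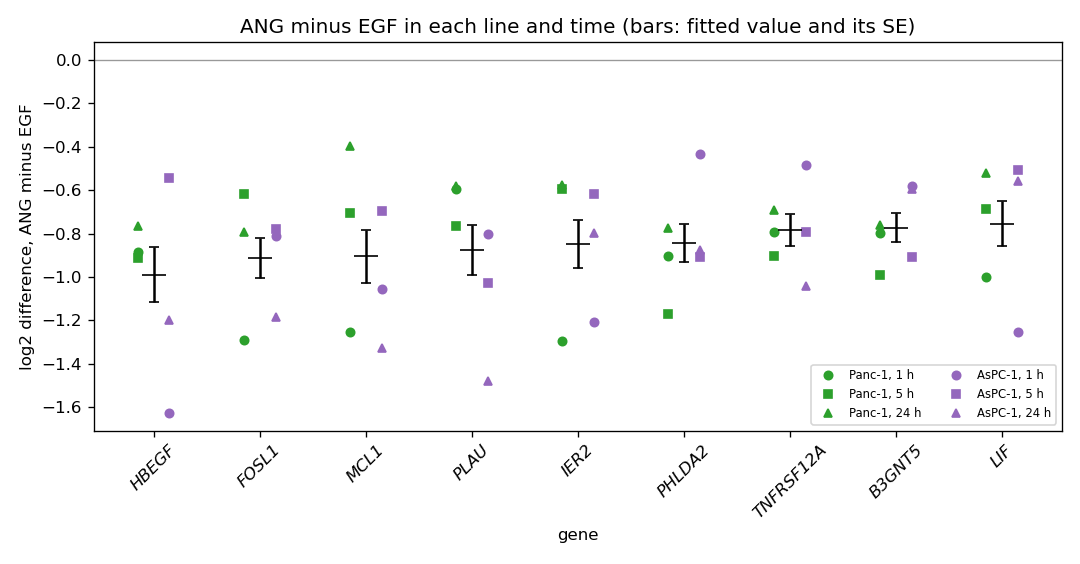
Difference ANG minus EGF in log2(RPKM + 1) for 9 named genes lower with ANG, 1 point per pair (Panc-1 green, AsPC-1 purple; circles 1 h, squares 5 h, triangles 24 h), with bars for the fitted value ± SE. All 6 points of each gene lie below 0, with fitted values from -0.99 for HBEGF to -0.76 for LIF.

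Of the 21 immediate-early genes 3 were lower with ANG (FOSL1, IER2 and MCL1), 0 were higher, and 11 were lower adjusted over the list alone. The mean over the 6 pairs of the list's median was -0.53 ± 0.42 (SD) and lay below 0 in 6 of 6 pairs. An exact two-sided sign-flip test gave p = 0.031, the smallest that 6 pairs allow, and 0.0799 after Benjamini-Hochberg adjustment over 23 lists, of which 0 passed. With that smallest p no list could pass the adjustment unless most of the 23 lists reached it, whatever the size of its difference. The invasion genes (-0.54 ± 0.46), the MAPK feedback genes (-0.29 ± 0.18), the NF-kB genes (-0.28 ± 0.14), the ATF4 genes (-0.22 ± 0.26), the cholesterol genes (-0.15 ± 0.11), the ribosome biogenesis genes (-0.12 ± 0.07), the mesenchymal markers (-0.09 ± 0.06) and, on the higher side, the FOXO targets (0.32 ± 0.29) had the same 6 of 6 direction and the same exact p. By members, 2 of 12 invasion genes, PLAU among them, and 2 of 18 NF-kB genes were lower, 8 and 8 adjusted over the list alone, and of 7 genes of the EGFR family and its ligands HBEGF was lower, with 3 adjusted over the list alone. Of 18 MAPK feedback genes 0 passed over all genes and 6 were lower adjusted over the list alone. SPRY4 (-1.23 ± 0.20), DUSP1 (-1.16 ± 0.19) and CDKN1A (-1.16 ± 0.19) missed the threshold with adjusted p = 0.0843 each, and EGR1, whose difference was large at 1 h and smaller later, did not pass (-1.64 ± 0.44, adjusted p = 0.169). EGFR differed by -0.06 ± 0.05 (adjusted p = 0.581). The call count depended on the pairs: without any 1 pair of Panc-1, or without the 5 h pair of AsPC-1, 0 genes passed, and without the 1 h pair of AsPC-1 12 did. With low genes kept 0 passed, without limma's trend 8, without the 24 h libraries or with them alone 0, and with levels rescaled to genes of at least 400 bp 2 were higher and 8 lower.

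All 11 genes that fell after 1 h of ANG and all 15 that fell after 5 h were also among those that fell with EGF at that time, where 0.05 and 0.544 were expected of independent lists. In 20 simulations of unchanged groups against the same mock libraries a mean of 0.05 genes passed for ANG and 0 for EGF at 1 h, and 0.15 and 0 at 5 h. These are too few to have an overlap, so the part of the overlap that comes from the shared mock was not measured for these calls. Across genes, which are not independent replicates, the changes from mock with ANG and with EGF correlated in Panc-1 with r = 0.823, 0.880 and 0.661 at 1, 5 and 24 h, against 0.514, 0.518 and 0.510 in simulations without effects. The covariance was 0.210, 0.25 and 0.0788 against a simulated 0.0460, 0.0465 and 0.0454. In AsPC-1 r was 0.941, 0.883 and 0.484 against 0.501, 0.493 and 0.478, and the covariance 0.556, 0.622 and 0.0553 against 0.0452, 0.0448 and 0.0423. Each line had 1 mock library, so part of the excess may come from the shared controls, and at 1 h and 5 h the excess also holds the split of those times from mock. Between the lines, which share no library, the ANG changes of Panc-1 and the EGF changes of AsPC-1 correlated with r = -0.138, -0.192 and 0.345 at 1, 5 and 24 h. For the ANG changes of AsPC-1 and the EGF changes of Panc-1 r was -0.189, 4.92e-04 and 0.402. The ANG changes of the 2 lines correlated with r = -0.124, -0.0570 and 0.567, and the EGF changes with r = -0.147, -0.0962 and 0.347. At 24 h the median of genes under 400 bp was above mock in Panc-1 and AsPC-1, at 1.07 and 0.65 with ANG and 0.79 and 0.64 with EGF. The positive r at 24 h may thus come largely from short genes that were low in both mock libraries. Their part was not measured.

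Whether the difference between ANG and EGF depended on the line was tested as an interaction over the 6 pairs. With limma 0 genes passed (smallest adjusted p = 0.398, 1039 at an unadjusted p under 0.05). The genes with the largest differences, none past the test, were DUSP6 (-1.5 ± 0.18), BCL6 (-1.02 ± 0.14), DDIT4 (1.40 ± 0.24), G0S2 (1.5 ± 0.31) and the protease inhibitor TFPI2 (-0.72 ± 0.13). DUSP6 with ANG and with EGF stood at 13.7 and 46.0 RPKM at 1 h in Panc-1 and at 91.8 and 72.9 RPKM in AsPC-1. Of the lists, camera called the MAPK feedback genes (median -0.49, adjusted p = 0.00833; adjusted p = 0.755 with an estimated correlation), and 0 of their members passed. A single gene passed without the 24 h pair of Panc-1.

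Change over time was tested within the 4 courses of each line and ligand, which does not use the mock libraries. It does not avoid the split of the libraries, as those of 1 h and 5 h stood apart from those of 24 h. A change between 1 h and 24 h may thus also hold the culture or handling of the dishes, which was not separated from time. Between 1 h and 5 h 0 genes passed with limma (smallest adjusted p = 1, 149 at an unadjusted p under 0.05). Unchanged genes would give a share of 0.05 of the 13427 tested, which is more than 149. The spread of this fit also holds the changes to 24 h that differed between the lines. The 0 therefore does not show that 1 h and 5 h were alike. The named genes at the ends, none past the test, were FOSB (-1.57 ± 0.70), EGR1 (-1.38 ± 0.57), the kinase WEE1 (-0.74 ± 0.50) and E2F1 (-0.63). The invasion genes had a median of 0.24 (camera adjusted p = 7.47e-05) and the G1/S genes one of -0.41 (camera adjusted p = 0.00221), with adjusted p of at least 0.788 with an estimated correlation and 0 members past the test. Within AsPC-1, a contrast chosen after seeing the data, 23 of 29 G1/S genes (median -0.69) and 14 of 24 G2/M genes (median -0.63) fell adjusted over the list alone and 0 over all genes. Within Panc-1 0 did either way (medians -0.11 and -0.16), and the difference between the lines was not tested for this interval.

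Between 1 h and 24 h, 462 genes rose and 392 fell in the 4 courses together (3380 at an unadjusted p under 0.05). The cholesterol synthesis genes DHCR7 (1.58 ± 0.11, adjusted p = 0.00202), SC4MOL (1.53 ± 0.12), MVD, a decarboxylase (1.35 ± 0.31), and FDFT1 (1.18 ± 0.12) were higher at 24 h in 4 of 4 courses. So were ACAT2 (2.17 ± 0.31), FADS2 (1.79 ± 0.16), the acetyl-CoA synthetase ACSS2 (1.65 ± 0.23) and the stearoyl-CoA desaturase SCD (1.25 ± 0.13), which belong to 0 of the lists tested. DHCR7 stood at 49.9 and 144 RPKM at 1 h and 24 h of ANG in Panc-1 and at 7.51 and 20.2 RPKM in AsPC-1. Of the 21 cholesterol genes 14 rose, 0 fell and 18 rose adjusted over the list alone (median 0.83, camera adjusted p = 1.91e-15; adjusted p = 0.0836 with an estimated correlation). Among ribosome biogenesis genes 9 of 31 fell, with RRP12 at -1.18 ± 0.15 (adjusted p = 0.0114) and the nucleolar protein NOP56 at -1.21 ± 0.25, and 23 fell adjusted over the list alone (median -0.54, camera adjusted p = 3.43e-13; adjusted p = 0.161 with an estimated correlation). Of the 16 unfolded protein response genes 5 fell, with HSPA5 at -0.80 ± 0.13, HYOU1 at -0.68 and SDF2L1 at -0.60, and 9 fell adjusted over the list alone. FOSL1 (-1.52 ± 0.24) was the 1 immediate-early gene of 21 that fell, and 6 fell adjusted over the list alone. The cytochromes CYP1A1 (-1.29 ± 0.16) and CYP1B1 (-1.30 ± 0.20) and the amino-acid transporter SLC7A5 (-0.85) fell too. Of 13 FOXO targets INSR (1.01 ± 0.22) and PIK3IP1 (0.87 ± 0.19) rose, and of 22 interferon-stimulated genes 2 rose (IRF9, 0.65, and BST2, 0.40). Of 19 genes of hypoxia and glycolysis PFKFB4, a regulator of glycolysis, rose (0.94) and 1 fell. Of the 854 genes, all had the same sign within each line, 692 passed in Panc-1 alone and 786 in AsPC-1 alone. These counts use the libraries that chose the genes and are no separate support. Without the Panc-1 ANG or EGF course 0 passed, without the AsPC-1 ANG course 3 and without the AsPC-1 EGF course 73. With each library centred on its median 450 rose and 516 fell. With levels rescaled to genes of at least 400 bp, chosen after seeing the data, 749 rose and 416 fell. The balance of directions depended on the scaling.

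For many genes the change from 1 h to 24 h, which runs along the split of the libraries, differed between the 2 lines. In the test of the difference between lines 1861 genes changed more upward in Panc-1 and 2979 more upward in AsPC-1 (limma, 6271 at an unadjusted p under 0.05), values given here as Panc-1 minus AsPC-1. The largest differences were those of replication-dependent histone genes, whose near-identical copies make single genes uncertain, with HIST1H1D (-7.06 ± 0.42) and HIST1H1B (-7.06 ± 0.54) at the end of the ranking. Among genes of division, the topoisomerase TOP2A differed by -5.12 ± 0.36 (adjusted p = 1.76e-04), the centromere protein CENPF by -5.13 ± 0.43, the spindle proteins HMMR by -4.96 and NUSAP1 by -4.82, the ribonucleotide reductase subunit RRM2 by -4.70 ± 0.32 and TYMS by -4.12. TOP2A stood at 46.7 RPKM in mock, 182 at 1 h and 39.4 at 24 h of ANG in Panc-1, and at 129, 8 and 112 RPKM in AsPC-1, and with EGF at 181 and 53 RPKM in Panc-1 and 10.8 and 73.9 in AsPC-1. On the other side stood the cytokine IL32 (3.60 ± 0.17, adjusted p = 1.28e-04), the transglutaminase TGM2 (3.30 ± 0.25), the actin-binding protein TAGLN (3.15 ± 0.23), ANGPTL4 (3.10 ± 0.29), the lipocalin LCN2 (2.99 ± 0.23) and cyclin D1, CCND1 (2.51 ± 0.13). DUSP6 differed by -2.56 ± 0.22 and EGFR by -0.37 ± 0.12 (adjusted p = 0.0498).

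By list, 24 of 24 G2/M genes had a lower difference (median -4.11, camera adjusted p = 7.78e-16), as did 11 of 11 histone genes (median -4.67) and 26 of 29 genes of G1/S and DNA replication, with 1 higher (median -2.29). All of them lost the list call with an estimated correlation (adjusted p = 0.464 with an estimated correlation). Within Panc-1, 24 of the 24 G2/M genes fell between 1 h and 24 h (median -1.60), and within AsPC-1 24 of 24 rose (median 2.49). Of 20 ATF4 genes 14 had a lower difference (median -1.25), among them SESN2 (-4.69 ± 0.45), TRIB3 (-4.46 ± 0.66) and CHAC1 (-3.70). Within Panc-1 13 ATF4 genes fell and within AsPC-1 9 rose and 2 fell. Of 12 heat shock genes 6 were higher (median 0.59), including HSPA8 (1.89) and the near-identical copies HSPA1A and HSPA1B (2.59 and 2.55, uncertain), and of 18 NF-kB genes 7 were higher and 1 lower (median 0.45), with CSF2 at 1.62 and IL8 at 1.52. Of 31 ribosome biogenesis genes 13 were higher and 2 lower (median 0.49), and of 13 FOXO targets 7 were lower (median -0.85). With centred libraries 3029 genes were higher and 2374 lower, and with rescaling to genes of at least 400 bp 2715 were higher and 2771 lower. Without the Panc-1 ANG course 1309 passed and without the Panc-1 EGF course 1518.

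**Figure D4:**
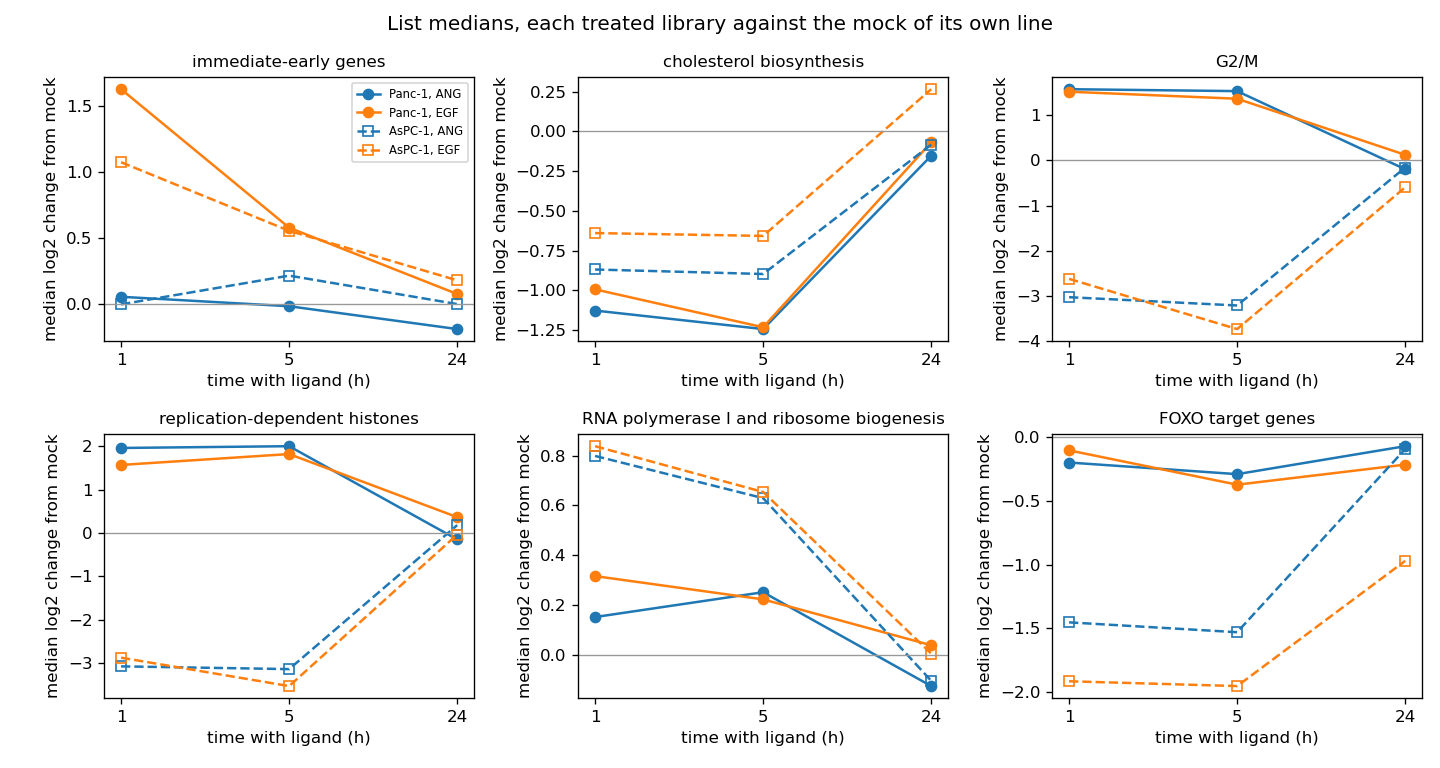
Median log2 difference from the mock of the same line for 6 gene lists at 1, 5 and 24 h (Panc-1 solid with filled points, AsPC-1 dashed with open points; ANG blue, EGF orange). G2/M and histone genes were above mock in Panc-1 and below it in AsPC-1 at 1 h and 5 h (G2/M 1.58 and -3.03 at 1 h of ANG), immediate-early genes were highest at 1 h of EGF (1.63 and 1.07), and cholesterol genes were low at 1 h and 5 h in both lines.

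Whether the change from 1 h to 24 h depended on the ligand was tested over the same 4 courses, and 0 genes passed (limma, smallest adjusted p = 1.00, 151 at an unadjusted p under 0.05). The largest differences, given as ANG minus EGF and not past the test, were those of the immediate-early genes FOSB (3.09 ± 0.83), NR4A1 (3.09 ± 0.58) and EGR1 (2.70 ± 0.58), and on the other side the integrin genes ITGA2 (-1.04) and ITGA5 (-0.95) and the collagenase MMP1 (-1.01). Of the 21 immediate-early genes 0 passed over all genes and 4 were higher adjusted over the list alone (median 0.80, camera adjusted p = 1.22e-16; adjusted p = 0.259 with an estimated correlation). The invasion genes had a median of -0.61 (camera adjusted p = 1.08e-07; adjusted p = 0.657 with an estimated correlation). In simulated data with the spread of this fit 0% of genes changed 2-fold were recovered, so this test had little power.

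The 2 lines were compared over the 7 matched conditions. Most mesenchymal markers were higher in Panc-1 and most epithelial markers higher in AsPC-1. The chemokine CCL2 (7.65 ± 0.09, limma adjusted p = 3.25e-10), the imprinted RNA H19 (6.92), the lactate dehydrogenase subunit LDHB (6.82), the adhesion molecule L1CAM (6.77), the gelatinase MMP2 (6.71 ± 0.07), APOE (6.68) and ICAM1 (6.52 ± 0.17) were higher in Panc-1 in 7 of 7 conditions. The hemidesmosome collagen COL17A1 (-6.56 ± 0.07, adjusted p = 3.25e-10), the cadherin CDH17 (-6.33), FERMT1 (-6.31), the tetraspanin TSPAN8 (-6.25), CEACAM6 (-6.20) and the laminin chain LAMB3 (-6.15 ± 0.34) were higher in AsPC-1. In all 5313 genes were higher in Panc-1 and 3930 in AsPC-1 (9592 at an unadjusted p under 0.05, median of all genes 0.13). Of 17 epithelial markers 14 were lower and 1 higher in Panc-1, with EPCAM at -4.98 ± 0.08 and the protease ST14 at -5.41. Of 8 mesenchymal markers 6 were higher and 1 lower, with SPARC at 5.18 ± 0.07 and CDH2 at 4.34 against SNAI2 at -5.06. Of 18 NF-kB genes 13 were higher and 2 lower, of 21 cholesterol genes 15 and 2, of 22 interferon-stimulated genes 15 and 4, and of 20 ATF4 genes 13 and 1, with the serine synthesis enzyme PHGDH at 5.22 ± 0.10. Of 12 invasion genes 4 were higher and 8 lower, LAMB3 among the latter. Of 73 ribosomal protein genes 13 were higher and 40 lower.

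The receptor EGFR was lower in Panc-1 (-1.5 ± 0.12, adjusted p = 6.79e-06), as were its partner ERBB3 (-4.77 ± 0.40), the ligand TGFA (-4.92), the ERK phosphatases DUSP4 (-5.36) and DUSP6 (-3.07 ± 0.48), FOS (-2.42 ± 0.22) and MYC (-1.66 ± 0.16). The ANG gene was higher in Panc-1 (0.52 ± 0.09, adjusted p = 6.59e-04), while RNH1 (0.14, adjusted p = 0.0801), PLXNB2 (0.03, adjusted p = 0.737) and CDKN1A (-0.10, adjusted p = 0.716) did not pass. An exact two-sided sign-flip test over the 7 conditions passed for 11 lists (p = 0.016, the smallest 7 conditions allow, and 0.0327 after adjustment), each with the same direction in 7 of 7. Their mean medians were 1.43 for NF-kB genes, 1.09 for cholesterol genes, 0.84 for interferon-stimulated genes, 0.62 for mesenchymal markers, 0.53 for unfolded protein response genes, 0.47 for p53 targets, -0.33 for ribosomal proteins, -1.25 for epithelial markers and -1.26 for invasion genes. Among them were 2 lists of markers of other cell types with few members: 3 measured fibroblast genes had a mean median of 0.23, and 3 leukocyte genes, LYZ among them (-5.58), one of -0.89. With the list's mean in place of its median the fibroblast value turned to -0.83, below 0 in 7 of 7, and the leukocyte value was -2.35. The ribosomal proteins then did not pass (-0.22, adjusted p = 0.0513), while the EGFR family and ligands (-1.46) and the ATF4 genes (1.64) did. Of endothelial and acinar markers 1 gene each was measured and of mitochondrial genes 0, and these lists were not tested.

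Set side by side with mock by a 2-fold difference, a description of single libraries with no replicate check, the sets of the 2 ligands were counted at each time. Both differences use the same mock library, so part of any overlap may come from it. In 20 simulations of unchanged libraries sharing a mock, means of 151 higher and 145 lower genes in Panc-1 and of 149 and 152 in AsPC-1 were in both sets, from sets of 391 to 406 genes. In Panc-1 at 1 h 506 genes were at least 2-fold higher with ANG and 452 with EGF (337 in both, 17.0 expected of independent lists), and 256 and 284 lower (167 in both, 5.41 expected). At 5 h 550 and 522 were higher (408 in both, 21.4 expected) and 325 and 453 lower (235 in both, 11 expected). In AsPC-1 at 1 h 639 and 702 were higher (495 in both, 33.4 expected) and 1472 and 1609 lower (1274 in both, 176 expected). At 5 h 672 and 708 were higher (345 in both, 35.4 expected) and 1630 and 1932 lower (1494 in both, 235 expected). Genes under 400 bp made up part of the higher sets, here counted with a mean of at least 1 RPKM over the 2 libraries. In AsPC-1 they were 300 of 623 with ANG and 214 of 686 with EGF at 1 h, and 326 of 654 and 35 of 696 at 5 h. In Panc-1 they were 142 of 485 and 38 of 434 at 1 h, and 230 of 530 and 211 of 498 at 5 h. The overlaps of the higher sets thus also depend on the short RNAs of single libraries. At 24 h 344 and 267 were higher (220 in both, 6.84 expected) and 13 and 25 lower (5 in both) in Panc-1. In AsPC-1 190 and 325 were higher at that time (147 in both, 4.60 expected) and 6 and 370 lower (1 in both). The sets in AsPC-1 at 24 h and the lower ones in Panc-1 at 24 h were smaller than the simulated sets, which limits their overlap. Of the 190 higher ANG genes in AsPC-1 at 24 h 147 were shared. In the simulations a mean of 37.6% of the first higher set in AsPC-1 was shared. Sets far from the simulated sizes cannot be set against them closely. The counts of longer genes also require a mean of at least 1 RPKM over the 2 libraries, a filter not used for the overlaps above. Among such genes of at least 400 bp, 97 were higher and 349 lower after 24 h of EGF in AsPC-1, against 4 and 0 after 24 h of ANG. In Panc-1 17 and 8 stood against 7 and 0.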

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

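The tests of the explanations of the 3 patterns, with the rescaling to longer genes, the ratios between ligands and the classes of short genes, were chosen only after the results were seen, while the interaction tests, the sign flips of lists, the centring and the counts over other splits were fixed in advance.

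Several results stood out because the lines moved apart over time. The count of genes whose change from 1 h to 24 h depended on the line was 4840. In 6 lists every course of one line moved one way and every course of the other the opposite way, with median differences Panc-1 minus AsPC-1 of -4.11 for G2/M genes, -4.67 for replication-dependent histones, -2.29 for G1/S and DNA replication genes, -1.25 for ATF4 genes, 0.59 for heat shock genes and 0.45 for NF-kB genes. The G2/M medians of the courses ran from -1.76 to -1.44 in Panc-1 and from 2.11 to 2.88 in AsPC-1. For single members the interaction was tested, and for the list medians the sign of each course is a description that was not tested.

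The first pattern is that the 1 h and 5 h libraries stood apart from mock and 24 h in both lines, with G2/M genes moving opposite ways in the lines. RNA of the other line in these libraries is argued against, because genes high in the other line's mock (at least 50 RPKM) and low in the own mock (at most 1 RPKM; 34 and 25 genes, a limit loosened after a stricter one left 0 genes) stood at a median of at most 0.967% of the other line's level. A shift in the share of short RNAs is also argued against, since after rescaling to longer genes the G2/M median of every such library was still at least 1.45 away from mock. In AsPC-1 the G2/M median from mock was already -3.03 with ANG and -2.63 with EGF at 1 h, against -3.22 and -3.74 at 5 h. For a ligand to cause this, most mRNA of these genes would have to be lost within 1 h. That argues against a ligand response as the whole source in AsPC-1. The culture or handling of the dishes sampled at 1 h and 5 h may be the source. A part played by either ligand cannot be told apart from it, because the time of the mock libraries was not given and 0 of them are labelled 1 h or 5 h. With culture or handling as the source the ligands should give like shifts. The ratio of the G2/M median at 1 h of ANG to that at 1 h of EGF was 1.04 in Panc-1 and 1.15 in AsPC-1, which a shared ligand response would give as well.

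The second pattern is that the median of the immediate-early genes was lower with ANG than with EGF in 6 of 6 pairs, though only 3 of 21 members passed and the adjusted sign-flip p of 0.0799 did not. With 6 pairs a list could pass that adjustment only if most lists reached the smallest p, so the adjusted p cannot decide on this list alone. Library scaling and short RNAs are argued against as the whole cause, since the list's median stayed below 0 in all 6 pairs when libraries were centred and when they were rescaled to longer genes, with a highest value of -0.088 in the 5 h pair of AsPC-1. A weaker form of the same response, by dose or potency, was not visible at 1 h but is not excluded. The ratio of the list's median at 1 h of ANG to that at 1 h of EGF was 0.0340 in Panc-1 and -0.0018 in AsPC-1. Both lie under the share that was set for such a response. A single dose of each ligand and 3 times keep open both a response too small to see and one that peaked at another time. In the 32 splits that exchange ANG and EGF within pairs, the real one gave 21 genes and the highest other 1. This is the most extreme result that 32 splits allow. The count is over all genes, 3 of them immediate-early, and is no test of the list.

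The third pattern is that short RNA genes were higher at 24 h of ANG than in mock. The rise was not particular to 24 h of ANG. At 1 h and 5 h of ANG the median of short genes from mock was 0.62 and 0.74 in Panc-1. In AsPC-1 it was 0.96 and 1.08. With EGF it was -0.15 and 0.78 in Panc-1 and 0.71 and 0 in AsPC-1 at these times. A response of short RNAs to ANG and not to EGF is argued against, since the median of short genes at 24 h of EGF was 0.79 in Panc-1 and 0.64 in AsPC-1, ratios to the ANG values of 0.734 and 0.983. Recovery of short RNAs that differed between libraries may be the source: the lowest median of the 5 small RNA classes over both ANG libraries was 0.29, that of microRNAs in AsPC-1. The 28 short genes outside these classes, left out of that test, stood at 0.39 in Panc-1 and 0.047 in AsPC-1, so not all short genes rose alike. Mock was 1 library per line, so a low recovery in mock and a shared treatment response stay open. Neither alone covers every library, as short genes were not raised at 1 h of EGF in Panc-1 or at 5 h of EGF in AsPC-1.

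For the comparison of the lines 1 of the 64 splits gave as many genes as the real 9243, with 679 as the highest other. Exchanging the lines puts their differences into the spread, so fewer genes in the other splits were to be foreseen. The 7 conditions repeat the same 2 lines, so the splits cannot decide on chance beyond these libraries. The other comparisons have too few splits for a share under 0.05. For 24 h against 1 h the real count was 854 and the highest other 0 over 8 splits (1 as large), and for the line-dependent change 4840 and 0 over 3 splits (1 as large). For 5 h against 1 h, 8 of 8 splits gave as many as the real 0 genes, with 0 as the highest other. For the line-dependent difference of ANG and EGF it was 10 of 10 splits, with 1 as the highest other. For the ligand-dependent change over time it was 3 of 3, and the highest other, 4840, came from the split by line, which points to the structure of the samples.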

How the results depend on the processing

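The settings with rescaling to genes of at least 400 bp, without 24 h or without 1 h and 5 h libraries, with single lines or ligands, and camera for ANG against EGF were chosen only after the data were seen, and the cause was not tested where none is named. Of the counts and correlations recomputed 132 stayed within 1.5-fold (counts, those of 0 that stayed 0 included) or 0.1 (correlations) of their value and 100 moved. Depth limits low genes: 1 read in 2 kb was worth 0.0210 to 0.0448 RPKM. Leaving out libraries gives fewer of them, with the lone library assumed to vary like the rest.

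With each library centred on its median, ANG at 1 h gave 0 genes, ANG at 5 h 0, EGF at 1 h 35, EGF at 5 h 168 and the EGF mean 0. Without the filter ANG at 1 h gave 6, EGF at 1 h 52, EGF at 5 h 369, EGF at 24 h 1, the EGF mean 103, ANG against EGF 0 and its line dependence 1. Without the trend ANG against EGF gave 8. With a pseudocount of 0.1 ANG at 1 h gave 7, ANG at 5 h 26 and EGF at 1 h 52. With genes of at least 400 bp ANG at 1 h gave 0, ANG at 5 h 9 and ANG against EGF 10. Without the 24 h libraries ANG gave 0 at 1 h and 5 h, EGF 0 at 1 h and 302 at 5 h, and ANG against EGF 0. Without the 1 h and 5 h libraries the EGF mean and ANG against EGF gave 0. Within Panc-1 and within AsPC-1 ANG against EGF gave 0, 24 h against 1 h gave 3566 and 5464, and 5 h against 1 h gave 2 in Panc-1. The ANG and EGF courses alone gave 0 for 24 h against 1 h.

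Leaving out 1 library, pair or course gave 0 for ANG at 1 h and at 5 h, 0 to 2 for EGF at 1 h, 0 for EGF at 5 h, 0 to 226 for the EGF mean, 0 to 14 for ANG against EGF, 0 to 1 for its line dependence, 0 to 73 for 24 h against 1 h, 1309 to 4855 for the line-dependent change and 8530 to 9094 for the lines. With a pseudocount of 10 the counts of 2-fold genes in Panc-1 were 223, 294, 173, 270 and 140 (ANG 1 h and 5 h, EGF 1, 5 and 24 h) and in AsPC-1 702, 802, 112, 705, 840 and 254 (ANG, then EGF). With an estimated correlation 0 lists were called in all 12 comparisons tested, against 6, 7, 0, 11, 10, 8, 7, 11, 4, 8, 11 and 8, and camera at the preset value called 13 lists for ANG against EGF. With a list's mean in place of its median the fibroblast list between the lines turned from 0.23 to -0.83. Over the upper range of expression, the correlation of ANG with EGF from the shared mock was 0.608 in AsPC-1 at 24 h. Simulations without effects gave 0.515 there. Without a shared library, correlations were -0.295 and 0.513 for Panc-1 ANG with AsPC-1 EGF at 5 h and 24 h. They were -0.293 and 0.639 for AsPC-1 ANG with Panc-1 EGF at 1 h and 24 h. For the 5 h minus 1 h changes of Panc-1 the value was 0.411. Between the lines correlations were 0.780 for ANG at 24 h and -0.248 and 0.523 for EGF at 1 h and 24 h. Short genes were not left out of these correlations, and their part in the 24 h values was not measured.

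Of the named genes' values under the alternatives, 1691 kept their sign and side of the threshold, 714 kept the sign without passing, 3 passed in addition and 17 changed sign, all of genes that had not passed. Centred, EGR1 at 1 h of ANG was at 0.043, FOS at 24 h of ANG at 0.072 and PLXNB2 between the lines at -0.075. Leaving out 1 library, at 1 h of ANG EGR1 ran from -0.30 to 0.066 and FOS from -0.74 to 0.049, both highest without the AsPC-1 ANG library. At 24 h of ANG EGFR ran from -0.41 to 0.064 and FOS from -0.27 to 0.24, both highest without the Panc-1 ANG library, and EGR1 from -0.0040 (without the Panc-1 mock) to 0.14. FOS at that time was at 0.22 without the AsPC-1 mock and at 0.059 over genes of at least 400 bp. DUSP6 at 1 h of EGF ran from -0.95 (without the Panc-1 EGF library; -0.47 without the Panc-1 mock) to 1.87. EGFR was 0.0015 for ANG against EGF within AsPC-1. Between the lines CDKN1A ran from -0.26 to 0.017 (highest without the 24 h EGF pair; 0.015 without that of 5 h) and was at 0.25 without the 1 h and 5 h libraries, and PLXNB2 was at -0.0052 without the 24 h libraries.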

Other observations

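The stretch of chromosome 19 described here was chosen after its values were seen, and its test was chosen then too.

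Genes of 1 stretch of chromosome 19 (hg19, 39833108 to 40791265, from SAMD4B to AKT2) were far higher in Panc-1 than in AsPC-1. It held 19 genes of at least 400 bp and a mean of at least 1 RPKM, with a median log2 difference of 4.05 and a range of 2.95 to 4.93. They included the transcription elongation factors SUPT5H (3.66) and PAF1 (4.05), the mRNA decay factor ZFP36 (2.95), the ribosomal protein gene RPS16 (3.93, uncertain because of processed copies), the nucleolar methyltransferase FBL (4.35), the proteasome subunit PSMC4 (4.23), the Notch ligand DLL3 (4.93), the kinase MAP3K10 (4.60) and AKT2 (4.72), a kinase of the PI3 kinase pathway. The next genes on one side, LRFN1 (1.44), IL29 (1.87) and PAK4 (2.15), and on the other, PLD3 (-0.32) and PRX (0.57), differed less, while PAPL, beyond PAK4, stood at 3.23, within the range of the stretch. The stretch was extended while genes stood above 2, so that all 19 do so by construction, and low genes inside it were left out. The highest median over 9 neighbouring genes was 4.23, against 2.72 as the highest over 10913 genes in 100 shuffled gene orders. DNA copy number was not analysed here.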
